A study of Drosophila melanogaster with 2 samples.

How the data were processed

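The material was 2 biological replicates of male pupal wings of the transgenic Drosophila melanogaster line D2, 35 to 45 wings each, at 67% of pupal development. Per the labels' protocols, wings were lightly crosslinked for 1 min, homogenised, and the nuclei were processed by CUT&RUN with 1 µl of an antibody against H3K27ac. The 2 replicates form 1 group, and the labels call them biological. Alignment and peak calling were done by the authors, and the submitters' processing notes name Bowtie2, MACS2 and the build dm6. Their versions, the settings of the caller, the treatment of duplicate reads and the use of a control library are not given in the sources used here. The deposited data are 1 peak list per replicate, so peaks were called per replicate and not on pooled reads.

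The deposited positions are start, end and summit of each peak, which were turned into 1-based coordinates of dm6. The deposited fold is the ratio of the pileup at the summit to the background estimated by the caller. The deposited -log10 p and -log10 q are those of the peak caller, and the deposited score is a whole-number form of the -log10 q. The fold and the -log10 values belong to the authors' calls and were used to describe, rank and filter peaks within a list. The smallest -log10 q was 2.01 in replicate 1 and 2.04 in replicate 2. Peaks below the caller's threshold are not listed, so that the lists set no level for regions without a peak.

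Depth was recovered from the peak values. For each peak, the fold and -log10 p were solved for a whole-number pileup and a Poisson background, and 100% of the peaks of both lists were solved within 0.001 units of log10 p. The most frequent background was taken as the genome-wide value, 13.8 fragments in replicate 1 and 27.1 fragments in replicate 2. The median pileup was 52 and 73 fragments. The smallest listed fold was 1.49 in replicate 1 and 1.31 in replicate 2, which follows the deeper background of replicate 2. Total read numbers are not given in the sources used here. Intervals and tests take genes, peaks or positions as units and do not model the counting of fragments. Fragments without molecular identifiers are not independent molecules.

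Genes came from a RefSeq table for Release 6 of the genome, the assembly also called dm6, with 13922 protein-coding genes on the 6 arms X, 2L, 2R, 3L, 3R and 4. The table gives the start and end of each gene without strand, transcripts or exons. The planned windows around transcription start sites were therefore replaced by windows of 500 bp on each side of both gene ends, and exon and intron classes were merged into the gene interior. A gene was marked when a peak overlapped such a window in both replicates. The peaks of the replicates need not overlap each other or lie at the same end of the gene. Of the symbols in the fixed lists, 9 were matched through a synonym and 1 was not matched.

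Overlaps of at least 1 bp were counted with bedtools 2.31.1. Overlap between replicates and the location of summits were compared with 1000 random rotations along each arm, one-sided for overlap and two-sided for location. Lists of genes were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 25 lists and a threshold of 0.05. Among genes with no other gene end within 1 kb the adjustment ran over 23 lists, since 2 lists, glia and dosage compensation, had no such gene. The 25 lists were 8 of wing biology, 4 of housekeeping complexes, 12 of other cell types and 1 of Hox and retinal selectors. Heights and widths were compared by 100000 permutations of peaks or genes. X was compared with 2L, 2R, 3L and 3R. Genes and peaks are not replicates, so these tests describe the 2 libraries. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

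The rule named every gene of the pigmentation and tanning list. For other lists it allowed up to 4 marked genes with the highest mean percentile and, where under 90% were marked, up to 3 unmarked genes in alphabetical order. It further took the 15 genes with the highest minimum percentile over the replicates, the 10 genes with the longest covered length, and the 8 highest shared peaks over 2 kb from any gene end. The text gives a selection of these.

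Alternatives fixed beforehand were windows of 250 and 1000 bp, peaks with a -log10 q of at least 5, the 7230 top peaks of each list, marking in either replicate, leaving out each replicate, summits in place of intervals, genes with no other gene end within 1 kb, all 17684 annotated genes, a reciprocal overlap of 50%, summits within 250 bp and uniform random positions. The alternative limited to the 5' end of each gene was not run, because the gene table gives no strand. Added after seeing the data were the whole gene, autosomal genes alone, random lists matched in length, thinning of replicate 2 to the background of replicate 1, halving of the autosomal pileups, gene ends set by the summit for the comparisons of peaks, and a comparison of shared with unshared peaks within groups of like height and width. The length matching first used 10 length groups and was changed to the 100 nearest genes after that result was seen, and both are reported. The thinning first kept 46.4% of each replicate 2 pileup, by a background per bp of the shortest peak, and was changed to 51.0%, the ratio of the backgrounds, after a first run, and both are reported.

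The procedures were tested on simulated data. Simulated lists were drawn from the 13922 protein-coding genes, and simulated peaks were placed on the arms of the gene table. Simulated heights were normal random values. The simulated lists were larger than most lists used here, and their genes were marked independently. Fewer permutations and rotations were used than in the report. The rates below therefore do not carry over to small lists or to neighbouring genes that share a peak. Of 100 lists without an effect 6 were called, and of 100 with a planted effect 100 were called. For differences of medians the numbers were 9 and 91 of 100, for overlaps 3 and 50 of 50, and for gene-end shares 3 and 50 of 50. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.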

Results

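H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was mapped by CUT&RUN, in which a nuclease tethered to an antibody releases the marked chromatin. The tissue was the pupal wing of male Drosophila melanogaster at 67% of pupal development, from the transgenic line D2. The series description places this time at a stage when the activity of the spot element is repressed. There were 2 biological replicates of 35 to 45 wings each, with 1 list of peaks per replicate and 1 group, so the comparisons run between regions of the genome and between the replicates. Replicate 1 held 14461 peaks covering 5.06 Mb, with a median width of 278 bp and a median fold enrichment of 2.43. Replicate 2 held 26420 peaks covering 8.11 Mb, with a median width of 252 bp and a median fold enrichment of 2.07. The genome-wide background recovered from the peak values was 13.8 fragments in replicate 1 and 27.1 fragments in replicate 2, a ratio of 1.96, so that replicate 2 could list weaker peaks.

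The first comparison asked how far the replicates share their peaks. The highest shared peak on the chromosome arms lay on X at 22433026 to 22433171, with a fold enrichment of 22.1 in replicate 1 and 23.0 in replicate 2, and its nearest protein-coding gene was CG14621, 11056 bp away. Other high shared peaks over 2 kb from any gene end lay inside nAChRalpha3, a nicotinic acetylcholine receptor subunit, at X 8295443 to 8295918 (fold enrichment 9.44 and 7.50). A further one lay inside Pka-R1, a regulatory subunit of protein kinase A, at 3L 20823058 to 20823858 (8.93 and 7.16). Others lay far from genes, on 4 at 1318277 to 1319673 (8.24 and 6.72), 46518 bp from Cadps, and on 2R at 25285276 to 25286190 (7.28 and 6.58), 29958 bp from CG9380. The last gene or peak position on these arms was 1319676 and 25286190, so both peaks lay at the edge of the positions used. The highest peak on X was 146 bp wide in replicate 1. Off the arms, an unplaced scaffold held a shared peak of 11.6 and 9.56. No regions were excluded from the lists here, so these peaks are ranked by height alone and were not checked for mapping artefacts. Of the replicate 1 peaks, 11458 (79.2%) overlapped a replicate 2 peak, and of the replicate 2 peaks, 11802 (44.7%) overlapped a replicate 1 peak. On the arms, 1000 rotations of the replicate 2 list gave a mean overlap of 13.5% and a maximum of 15.5% against 79.2% observed (one-sided permutation p = 0.000999, the smallest these rotations can give). Across shared peaks, which are not independent, the Spearman correlation of fold enrichment between the replicates was 0.51. With an equal number of 7230 top peaks per list, the shared percentage was 55.7.

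The second comparison asked where the shared peaks lie. Gene ends held 4006 of the 11423 shared summits (35.1%), against 18.2% after rotation. Intergenic sequence held 1485 summits, a ratio of 0.496 to the rotated share of 26.2%. The interior of genes held 5932 summits (51.9%), against 55.6% after rotation. The gene-end and intergenic differences both had a two-sided permutation p of 0.000999, the smallest 1000 rotations can give, and the gene interior had p = 0.0020. The direction for gene interiors turned with a window of 250 bp (difference of 2.95 percentage points, permutation p = 0.0050) and was 0.298 percentage points in replicate 2 alone (permutation p = 0.720). The gene table used here gives no strand, so that a gene end is either end of an annotated gene and promoters were not separated from 3' ends.

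Peaks reaching a gene end were higher and wider than the other peaks within each list. In replicate 1, the median fold enrichment was 2.55 for 5670 gene-end peaks and 2.36 for 8755 other peaks, and the median widths were 316 and 258 bp. In replicate 2, the median fold enrichment was 2.12 for 9518 gene-end peaks and 2.04 for 16840 other peaks, and the median widths were 286 and 235 bp. The log2 differences were 0.11 and 0.05 (two-sided permutation p = 1e-05 for height and for width in each replicate, the smallest that 100000 permutations can give). A wider peak reaches a gene end more easily, so the classes were also set by the summit alone, a setting chosen after seeing the data. The median fold enrichment was then 2.54 against 2.38 in replicate 1 and 2.11 against 2.05 in replicate 2, and the width differences were 38 and 34 bp (permutation p = 1e-05 for each, the smallest they can give). Peaks are not replicates, so these tests describe each library.

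Unshared peaks lay less often at gene ends than shared ones. In replicate 1, 4741 of 11423 shared peaks (41.5%) and 929 of 3002 unshared peaks (30.9%) reached a gene end (Fisher's exact test, two-sided, p = 1.81e-26). In replicate 2, the figures were 4877 of 11768 (41.4%) and 4641 of 14590 (31.8%), with p = 8.74e-59 in the same exact test. With a reciprocal overlap of 50%, the differences shrank from 10.6 to 3.05 percentage points in replicate 1 (exact p = 0.000195) and from 9.63 to 6.42 in replicate 2 (exact p = 2.45e-23). Wider peaks overlap both more partners and more gene ends. With gene ends set by the summit, a setting chosen after seeing the data, the differences were 8.02 and 7.47 percentage points (exact p = 5.13e-17 and 7.98e-39). Among peaks of like height and width, also chosen after seeing the data, they were 3.73 and 3.91 percentage points (permutation p = 0.0002 and 0.0001, the latter the smallest that 10000 permutations can give). Unshared peaks were also low within their own list, at a median percentile of 30.8 in replicate 1 and 36.2 in replicate 2, against 55.5 and 69.1 for shared peaks.

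At the level of genes, 5474 of 13922 protein-coding genes (39.3%) had a peak within 500 bp of a gene end in both replicates. These are called marked genes, and their peaks in the replicates need not overlap. The list of replicate 1 marked 5989 genes and that of replicate 2 marked 8496, each including the genes marked in both. Among the 15 genes ranked highest in both lists were cta, a G protein alpha subunit (fold enrichment 7.14 in replicate 1 and 5.19 in replicate 2), and Tsp39D, a tetraspanin (6.11 and 4.27). Maf1, a repressor of RNA polymerase III, had 5.4 and 4.50. The splicing regulator mbl had 5.22 and 4.09, and the homeodomain genes Gsc and Optix had 4.86 and 5.01, and 4.79 and 3.96. The ionotropic receptor gene Ir48c had 5.53 and 5.05. CG2993 and sgll carried the same peak, as did the co-located CG30080, CG42662 and CG46433, so that 1 peak accounts for several names. The remaining genes of the 15 were CG9932, CG42788 and CG3649.

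Genes of wing biology were examined in 8 lists fixed before the data were examined. In the pigmentation and tanning list, 11 of 19 genes were marked (57.9%, against 39.3% of all other genes; adjusted exact p = 0.253). The laccase gene stw had fold enrichments of 3.61 and 4.63, the tyrosine hydroxylase gene ple 3.04 and 3.63, and the aspartate decarboxylase gene b 3.14 and 3.01, from a peak that also reached PolG1. Ddc, the dopa decarboxylase gene, had 2.93 and 2.11, and e, which encodes the enzyme joining beta-alanine to dopamine, had 2.05 and 2.18. The gene y, needed for black melanin, had 2.33 and 3.28, from a peak at its start in replicate 1 and from one at its other end in replicate 2. Dhpr had 3.98 and 2.99, from a peak that also reached Use1 and bol. Also marked was yellow-e, although its peaks in the replicates did not overlap, with 0 bp covered in both lists in the gene or within 2 kb. The genes yellow-h, yellow-b and yellow-d2 were marked through peaks that also reached CG31999, BuGZ and yellow-d. The tan gene t, speck and yellow-f2 had no gene-end peak in either replicate, yellow-e3 had one in replicate 1 and not in replicate 2, and Hn, Pu, yellow-c and yellow-f had one in replicate 2 and not in replicate 1. Away from the gene ends, speck held peaks of 3.44 and 3.59, Pu of 2.50 and 2.37, and e of 3.19 and 2.64. No such peak was listed for t or yellow-f2.

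Other wing lists were marked at rates from 9.09% to 66.7%. Wing patterning genes were marked in 20 of 35 cases (57.1%; adjusted exact p = 0.154), with kni at 3.57 and 3.45, wg at 3.30 and 3.02, and dpp at 3.14 and 3.31, while Delta and Egfr had no gene-end peak. Planar polarity and wing hair genes were marked in 12 of 18 cases (66.7%; adjusted exact p = 0.154), with the cadherin genes stan at 3.28 and 2.49 and ds at 2.88 and 2.50. Ecdysone response genes were marked in 12 of 24 cases (50.0%; adjusted exact p = 0.470), among them Eip75B at 3.24 and 2.54 and Eip93F at 2.89 and 2.77, whose peak also reached Theg. ZP-domain and chitin genes were marked in 11 of 24 cases (45.8%; adjusted exact p = 0.704), with the chitin deacetylase gene serp at 2.86 and 3.76. Cpr cuticle protein genes were marked in 28 of 70 cases (40.0%; adjusted exact p = 0.981), with Cpr92F at 3.77 and 3.77. Proneural and bristle genes were marked in 6 of 19 cases (31.6%; adjusted exact p = 0.762), with hry at 4.05 and 3.46 and with ac and amos unmarked. The Notch-responsive E(spl) complex was marked in 1 of 11 cases (9.09%; adjusted exact p = 0.176), at E(spl)m6-BFM, and in 5 of 11 cases by the list of replicate 2.

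Housekeeping lists did not pass the test either. Ribosomal protein genes were marked in 41 of 86 cases (47.7%; adjusted exact p = 0.253), with RpL10 at 4.52 and 2.74, and proteasome genes in 22 of 43 cases (51.2%; adjusted exact p = 0.253), with Prosbeta6 at 4.32 and 3.80. Vacuolar ATPase genes were marked in 13 of 33 cases (39.4%; adjusted exact p = 1) and dosage compensation genes in 3 of 5 (adjusted exact p = 0.539), namely msl-1, msl-2 and msl-3, of which msl-2 and msl-3 shared their peaks with neighbouring genes. Among genes of other cell types, odorant receptors were marked in 7 of 59 cases (11.9%, a difference of -27.6 percentage points from all other genes; adjusted exact p = 0.000141). Gustatory receptors were marked in 10 of 60 cases (16.7%, a difference of -22.8 percentage points; adjusted exact p = 0.00338). The odorant receptor peak at Or47a also reached the cuticle gene Cpr47Ea, and that at Or46a reached CG12917 and CG18011. The peaks at Or67a (3.64 and 3.63) and Or43a (2.77 and 2.60) were shared with no neighbouring gene. The peaks at Gr63a, Gr39b and Gr61a each reached a neighbouring gene.

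Markers of further cell types were marked in 2 of 19 photoreceptor genes (adjusted exact p = 0.0743), 3 of 20 muscle genes (adjusted exact p = 0.154), 2 of 14 fat body genes (adjusted exact p = 0.176), 3 of 15 hemocyte genes (adjusted exact p = 0.356) and 6 of 21 neuronal genes (adjusted exact p = 0.539). The muscle genes Mlc2 and Zasp66 were marked through peaks that also reached Rsod and GAPsec. Trachea genes were marked in 4 of 10 cases (adjusted exact p = 1), among them trh at 3.61 and 3.43 from a peak that also reached CG1233, and glia genes in 5 of 11 (adjusted exact p = 0.865), among them moody at 3.29 and 3.48. Germline and testis genes were marked in 7 of 26 cases (adjusted exact p = 0.385), accessory gland and seminal fluid genes in 14 of 47 (adjusted exact p = 0.385), and gut proteases in 5 of 25 (adjusted exact p = 0.176). Hox and retinal selector genes were marked in 4 of 13 cases (adjusted exact p = 0.732), among them abd-A at 3.44 and 4.05.

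Several of these counts depended on the replicate, with 5474 genes marked in both lists and 8496 marked by the list of replicate 2, whether or not by the other. That list marked 11 of 13 Hox and retinal selectors (a difference of 23.6 percentage points from other genes, adjusted exact p = 0.250) and 10 of 15 hemocyte genes (5.65 percentage points, adjusted exact p = 0.827), which turned the direction of both lists. It also marked 9 of 10 trachea genes, 9 of 11 glia genes, 24 of 33 vacuolar ATPase genes, 8 of 19 photoreceptor genes and 14 of 25 gut proteases. It marked 61% of other genes, and none of these lists passed (adjusted exact p = 0.250, 0.344, 0.344, 0.250 and 0.742). It further marked 45 of 70 Cpr genes, 18 of 24 ZP-domain and chitin genes, 14 of 59 odorant receptors and 17 of 60 gustatory receptors. Of these only the receptors, which lay below other genes, passed (adjusted exact p = 0.742, 0.344, 1.94e-07 and 4.52e-06). Muscle genes (6 of 20, adjusted exact p = 0.0349) and fat body genes (3 of 14, adjusted exact p = 0.0337) lay below all other genes by the list of replicate 2, and that of replicate 1 marked 4 of 14 fat body genes (adjusted exact p = 0.570).

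Over all 25 lists, Fisher's exact test (two-sided, Benjamini-Hochberg over the lists) called 0 lists above and 2 below all other genes, and 6 lists had an unadjusted p under 0.05. Restricting the test to the 2694 genes with no other gene end within 1 kb changed the calls to 3 above and 0 below in Fisher's exact test, with 0 lists below at an unadjusted p under 0.05 as well. The lists above were pigmentation and tanning (4 of 4 genes, adjusted exact p = 0.0204), wing patterning (15 of 25, adjusted exact p = 0.00144) and ribosomal proteins (8 of 10, adjusted exact p = 0.0023), against 22.6, 22.4 and 22.5% of the other isolated genes. Odorant receptors stood at 2 of 25 against 22.9% (adjusted exact p = 0.427) and gustatory receptors at 3 of 14 against 22.8% (adjusted exact p = 1). With an equal number of top peaks per list, odorant receptors stood at 5.08% and gustatory receptors at 6.67% against 18.6% of other genes, and neither list passed (adjusted exact p = 0.103 and 0.227). With a -log10 q of at least 5, planar polarity and wing hair genes lay above (adjusted exact p = 0.0290) and gustatory receptors did not pass (adjusted exact p = 0.0984). Among autosomal genes alone, a setting chosen after seeing the data, planar polarity and wing hair genes lay above and photoreceptor genes below (adjusted exact p = 0.0449 each), with 3 lists below in all.

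A wider definition, chosen after seeing the data, counted a gene as marked when a peak lay anywhere in it or within 500 bp of it in both replicates. Here too, the peaks of the replicates need not overlap. Wing patterning genes were then marked in 33 of 35 cases, planar polarity and wing hair genes in 17 of 18, ZP-domain and chitin genes in 22 of 24 and ecdysone response genes in 22 of 24. These 4 lists lay above all other genes (adjusted exact p = 2.2e-07, 0.000305, 0.000115 and 0.000115), and 7 lists lay below. Their genes are long, with median lengths of 21.3, 23.0, 9.86 and 24.0 kb against 2.16 kb for all protein-coding genes. Against random lists drawn from the genes nearest in length, their rates of 94.3, 94.4, 91.7 and 91.7% compared with 73.5, 68.0, 69.2 and 70.1% (adjusted permutation p = 0.0125, 0.0411, 0.0411 and 0.0427).

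**Figure D1:**
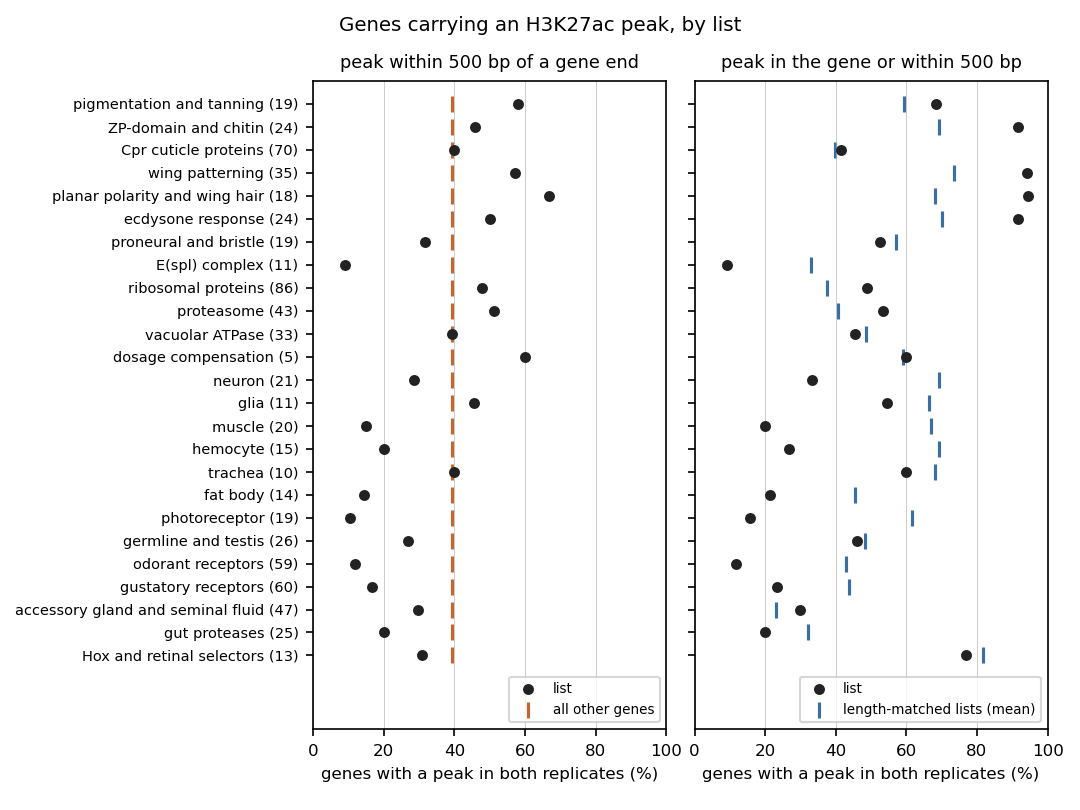
Percentage of the genes of each list with an H3K27ac peak in both replicates, with the number of genes in brackets (dots). Left, a peak within 500 bp of a gene end, with all other genes as vertical ticks near 39.3%; right, a peak in the gene or within 500 bp, with the mean of length-matched random lists as ticks, where wing patterning reaches 94.3% against 73.5%.

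The male wing carries 1 X chromosome, and X was compared with the large autosomal arms. On X, 312 of 2197 genes were marked (14.2%, 95% Wilson interval 12.8 to 15.7), against 5129 of 11645 on 2L, 2R, 3L and 3R (44.0%, 43.1 to 44.9). The difference was -29.8 percentage points (Fisher's exact test, two-sided, p = 5.74e-171). Replicate 1 gave 22.2% on X and 46.9% on the autosomes, and replicate 2 gave 28.1% and 67.3%. Chromosome 4 had 33 of 80 genes marked (41.2%). X held 56.7 peaks per Mb in replicate 1 and 61.4 in replicate 2, while the large autosomal arms held 115 to 125 and 220 to 241 and chromosome 4 held 74.3 and 121. Of the X peaks, 31.6% in replicate 1 and 75.6% in replicate 2 were called against the genome-wide background, compared with 13.5% and 14.9% on 2R and with 48.0% and 59.4% on chromosome 4.

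At the strongest gene-end peak, marked genes of X had a lower fold enrichment than marked autosomal genes. All X peaks together differed little in fold from all autosomal ones, but had lower median pileups. The median fold enrichment of the strongest gene-end peak was 2.53 on X and 2.74 on the autosomes in replicate 1, and 2.19 and 2.40 in replicate 2. The log2 differences were -0.11 and -0.13 (two-sided permutation p = 1e-05 in each, the smallest that 100000 permutations can give). Fold enrichment is taken over a background that stood at the genome-wide value for a larger share of X peaks than of autosomal ones. These heights therefore have unlike denominators. Over all peaks, the median fold enrichment was 2.41 on X and 2.43 on the autosomes in replicate 1, and 2.06 and 2.07 in replicate 2. The median pileup, which has no denominator, was 41 fragments on X and 51.5 to 55 on the large autosomal arms in replicate 1. In replicate 2 it was 58 on X and 72 to 76 on those arms. A lower background also lets peaks be called at a lower pileup. With a -log10 q of at least 5, the gene-end differences were -0.07 (permutation p = 0.0406) and -0.05 (permutation p = 0.0542). With isolated genes, of which 23 were marked on X, they were -0.03 (permutation p = 0.811) and -0.15 (permutation p = 0.0516).

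**Figure D2:**
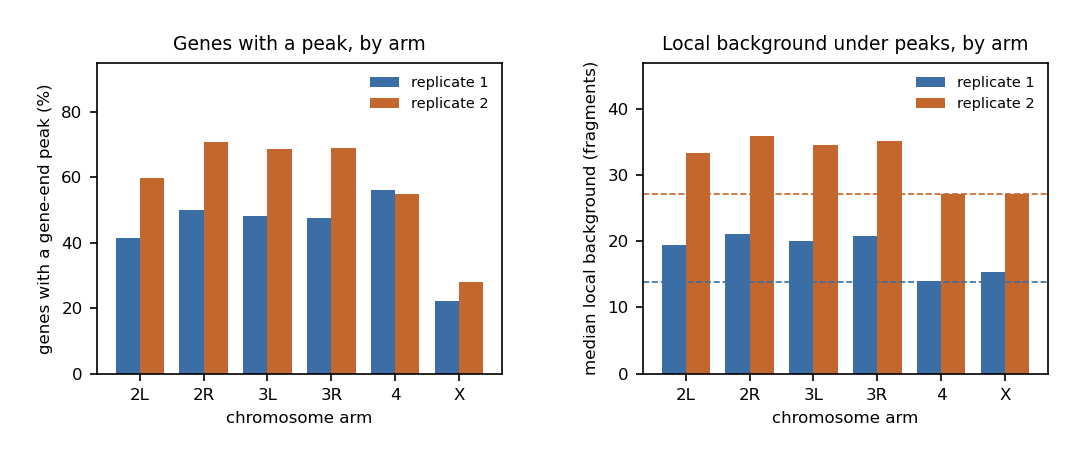
Left, percentage of protein-coding genes with a gene-end peak per chromosome arm and replicate, where X stands at 22.2% and 28.1%; right, median local background under the peaks, in fragments, with the genome-wide background of each replicate as a dashed line. On X the median lies at 15.4 fragments in replicate 1 and at 27.1, the genome-wide value, in replicate 2.

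The locus of interest was y, at X 356509 to 361245 in dm6, which shapes black pigment and whose wing and body enhancers lie in its 5' flank. Within 20 kb of y, replicate 1 had 7 peaks and replicate 2 had 6, of which 5 in each overlapped one in the other list. A peak in the 5' flank spanned 354418 to 355133 in replicate 1 (fold enrichment 3.11, -log10 q of 14.1) and 354166 to 355094 in replicate 2 (2.97, -log10 q of 18.2), with summits 1881 and 1961 bp before the gene start. A second flanking peak lay at 353802 to 354056 (2.53) and 353725 to 354040 (2.32). A peak over the gene start lay at 356321 to 356826 (2.33) and 356313 to 356822 (2.29). Within y, a peak spanned 359752 to 360668 in replicate 1 (2.72) and 359690 to 361127 in replicate 2 (3.28). A further shared peak lay at 345142 to 345310 (2.22) and 345119 to 345277 (2.35), within the annotated span of CG3777.

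Among all peaks of X, the 5'-flank peak stood at percentile 92.7 in replicate 1 and 97.6 in replicate 2, and the peak inside y at 78.7 and 98.9. No gene-end peak was listed for the neighbouring proneural gene ac. The annotated span of CG32816, X 316576 to 470726, covers the whole of y, so that a peak there lies in both genes by position. Reads between peaks were not used here, so the absence of a peak sets no bound on the signal.

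The peak lists also name a transgene contig, which had 6 peaks in replicate 1 and 7 in replicate 2, each overlapping one in the other list. Its highest peaks were 3969 to 4337 in replicate 1 (fold enrichment 3.47) and 3997 to 4743 in replicate 2 (3.31). A peak at 12017 to 12460 (2.50) in replicate 1 met one at 11852 to 12460 (3.27) in replicate 2. The sequence of the contig was not used here, so no feature was placed on it. Whether the transgene carries y sequence was not examined, and reads from any such sequence cannot be separated from those of the y locus.

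**Figure D3:**
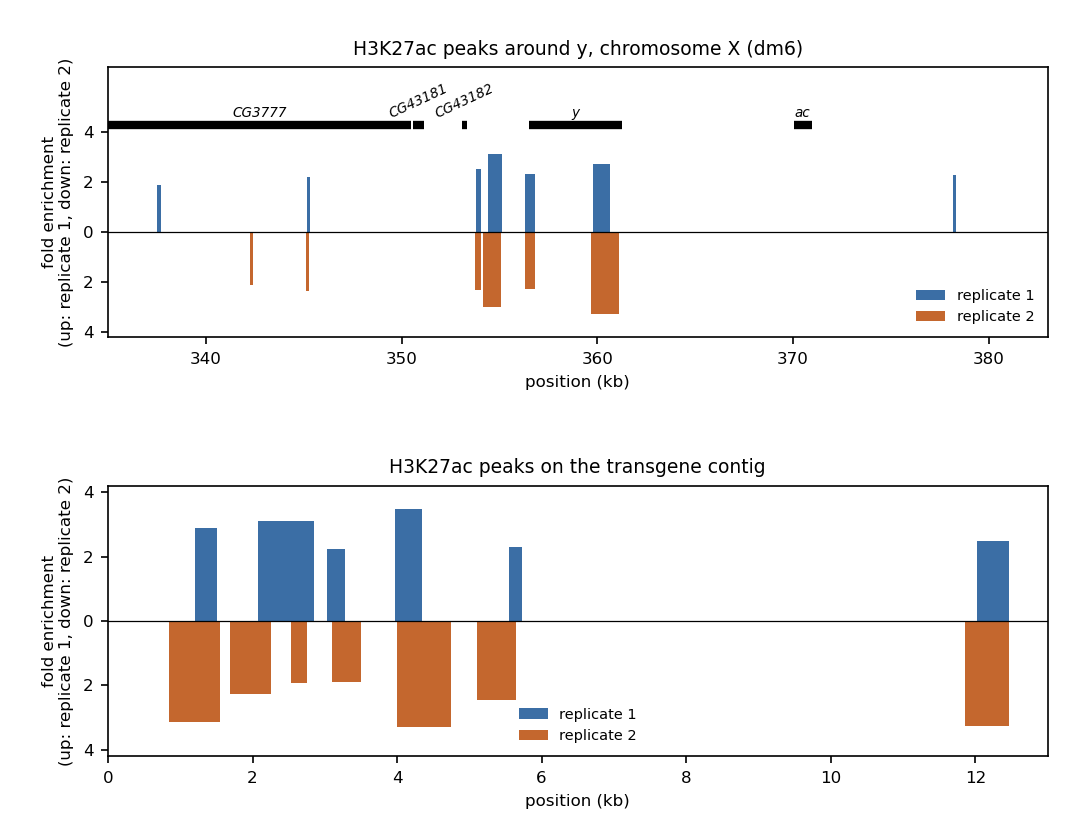
Top, H3K27ac peaks around y on X in dm6, drawn to scale with bar height as fold enrichment (replicate 1 upward, replicate 2 downward) and protein-coding genes as black lines, except CG32816, whose span covers the whole of y. Bottom, peaks on the transgene contig on the same scale of fold enrichment. The flanking and intragenic peaks of y reach 3.11 and 2.72 in replicate 1 and 2.97 and 3.28 in replicate 2.

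Genes were also ranked by the length covered by shared peaks, counted from 2 kb before to 2 kb after the gene. EcR, the ecdysone receptor gene, led over the sequence covered in both lists with 8541 bp, followed by the overlapping CG46467 and Glut4EF with 7682 bp each. EcR led in neither list alone, with 10329 bp in replicate 1 against 10680 bp for CG46467 and Glut4EF, and 11036 bp in replicate 2 against 15487 bp for heph. The TSC-22 family gene bun had 6228 bp, the Wingless receptor gene fz2 had 6221 bp, the RNA-binding protein gene sm had 6108 bp and the ubiquitin ligase adaptor gene rdx had 6059 bp. They were followed by heph (6000 bp), Snoo (5858 bp) and klar (5839 bp). These 10 genes had a median length of 100 kb, and of the top 10 by the list of replicate 2, 4 were in this ranking.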

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

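No test here was chosen after its result was seen, as only counts are given. Peaks outside the 6 arms enter the totals, percentiles and shared counts of whole lists, but not the tests of genes, location or height. They were listed because a signal appears in sequence that those tests leave out. The transgene contig is described above. The mitochondrial sequence had 3 peaks in replicate 1 and 13 in replicate 2, with a median local background of 66.8 and 258 fragments and a highest fold enrichment of 2.52 and 2.37. The Y chromosome had 1 peak in replicate 1 and 4 in replicate 2, with a highest fold enrichment of 3.30 and 4.62. Y scaffolds without a position had 8 and 15 peaks, with a highest fold enrichment of 8.16 and 9.31. Unplaced scaffolds had 16 peaks in replicate 1 and 18 in replicate 2, with a highest fold enrichment of 11.6 and 11.9. No control library was analysed here, so these peaks were not set against a background measured the same way.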

How the results depend on the processing

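The whole-gene, autosomal, length-matched, thinned and halved tests and those with gene ends of peaks set by the summit were chosen after the result was seen, and the other settings were fixed beforehand. Over all settings 423 values kept their direction and call, 49 changed direction, 36 became stronger, 8 became weaker and 25 moved. A count moved when it changed by more than 1.5 times, the shared percentage when it left its 95% interval, and the covered length when it changed by more than the SD between the replicates. No paired analysis was possible because there is 1 group. The alternative with the 5' end of each gene and the classes of exon and intron were not run, because the gene table gives no strand, transcripts or exons. Values for lists are differences from the other genes in percentage points, and where no reason is given the cause was not tested.

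With windows of 250 bp, proneural and bristle genes stood at 3.62, vacuolar ATPase genes at -3.73, trachea genes at -7.97, Hox and retinal selectors at 2.81, and summits inside genes at 2.95 against rotation. With 1000 bp, trachea genes stood at -10.9.

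With a -log10 q of at least 5, 1 list lay above (planar polarity and wing hair, 37.2, adjusted exact p = 0.0290) and 1 below. Gustatory receptors stood at -14.6 (adjusted exact p = 0.0984), Cpr genes at -0.998 and Hox and retinal selectors at 1.21. The log2 fold enrichment of X against autosomes was -0.0591, and 78.4% of replicate 1 peaks were shared.

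With the 7230 top peaks of each list, 2580 genes were marked, a count that falls because fewer peaks enter, and 0 lists lay below by Fisher's exact test. Odorant receptors stood at -13.5 (adjusted exact p = 0.103), gustatory receptors at -11.9 (adjusted exact p = 0.227), proneural and bristle genes at 2.52 and Hox and retinal selectors at 4.55. Of the peaks of replicate 1, 55.7% were shared.

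Marking in either replicate gave 9011 genes, which follows from the definition. Hemocyte genes stood at 1.94, accessory gland and seminal fluid genes at -20.1 (adjusted exact p = 0.0457) and Hox and retinal selectors at 19.9.

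Leaving out each replicate in turn gave 5989 to 8496 marked genes and 2 to 4 lists below. Muscle genes ranged from -31.1 to -23.1, fat body genes from -39.6 to -14.5, hemocyte genes from -23.0 to 5.65 and Hox and retinal selectors from -12.3 to 23.6. E(spl) genes ranged from -34.0 to -15.6, with 1 and 5 of 11 marked. Cpr genes ranged from -0.162 to 3.28, vacuolar ATPase genes from -3.63 to 11.7 and trachea genes from -3.02 to 29.0. Summits inside genes ranged from -1.78 to 0.298, and the median length covered in the top 10 genes from 9125.5 to 13152 bp.

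With summits in place of intervals, proneural and bristle genes stood at 0.276, vacuolar ATPase genes at -1.0 and trachea genes at -1.30.

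Among genes with no other gene end within 1 kb, 3 lists lay above and 0 below by Fisher's exact test. Pigmentation and tanning genes stood at 77.4, wing patterning at 37.6 and ribosomal proteins at 57.5. Odorant receptors stood at -14.9, gustatory receptors at -1.33, proteasome genes at -2.76, proneural and bristle genes at 4.54, neuronal genes at 10.6, germline and testis genes at 27.3, accessory gland genes at 4.54 and Hox and retinal selectors at 17.3. The log2 fold enrichment of X against autosomes was -0.0881.

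With the whole gene, 4 lists lay above and 7 below. ZP-domain and chitin genes stood at 41.9, wing patterning at 44.5, planar polarity and wing hair at 44.6 and ecdysone response at 41.9. E(spl) genes stood at -40.8, muscle at -29.9, photoreceptor at -34.1, accessory gland at -20.2 and gut proteases at -29.9. Cpr genes stood at -8.50, proneural and bristle genes at 2.75, ribosomal proteins at -1.05, vacuolar ATPase genes at -4.44 and Hox and retinal selectors at 27.1.

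With autosomal genes alone, 1 list lay above, planar polarity and wing hair at 36.0, and 3 below, with photoreceptor genes at -32.3 newly among them. Cpr genes stood at -1.63, vacuolar ATPase genes at -5.35 and trachea genes at -4.05.

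With replicate 2 thinned to the background of replicate 1, Cpr genes stood at -0.374 and 68.9% of replicate 1 peaks were shared. In the first form of the thinning, changed after a first run, the values were -1.06 and 66.9%.

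For gene ends against random lists matched in length, 4 lists lay below. Muscle genes stood at -31.2, photoreceptor genes at -35.2, vacuolar ATPase genes at -1.62, glia genes at -2.40, trachea genes at -5.23 and accessory gland genes at 6.86.

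For the whole gene against the nearest genes in length, 4 lists lay above and 6 below. ZP-domain and chitin genes stood at 22.5, wing patterning at 20.8, planar polarity and wing hair at 26.4 and ecdysone response at 21.6. Neuronal genes stood at -35.9, muscle at -47.0, hemocyte at -42.6, photoreceptor at -45.9, glia at -11.7, trachea at -8.23, vacuolar ATPase at -2.98 and accessory gland at 6.76. In the first form of the matching, by 10 length groups, again 4 lay above and 6 below. There, ZP-domain and chitin genes stood at 24.1, wing patterning at 20.3, planar polarity and wing hair at 26.1 and ecdysone response at 22.1. Neuronal genes stood at -35.1, muscle at -47.0, hemocyte at -41.8, photoreceptor at -45.5, glia at -11.8, trachea at -10.0, vacuolar ATPase at -3.75 and accessory gland at 4.81.

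With autosomal pileups halved, and their backgrounds halved to no less than the genome-wide value, X minus autosomes in marked genes was -0.193 percentage points. With a reciprocal overlap of 50%, 56.0% of replicate 1 peaks were shared, and with summits within 250 bp 72.2%, both of which follow from a stricter definition. With the reciprocal overlap, shared minus unshared peaks at gene ends was 3.05 percentage points in replicate 1 and 6.42 in replicate 2. With gene ends set by the summit it was 8.02 and 7.47, with sharing by summits as well 5.38 and 6.95, and among peaks of like height and width 3.73 and 3.91.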

Other observations

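The tests of the local background at y, of autosomal genes alone, of gene length and of heights over all X peaks were chosen after the result was seen, as was the use of the planned X height comparison as an explanation, while the bound for the halving of autosomal pileups was set before its result but after the data were examined. That use was set aside after its value was seen and then taken up again. The y tests were reworded after their values were seen, and the gene-length test was changed once after a first form.

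The lower share of marked genes on X may come from the single X dose of the male wing, measured against a genome-wide background. When 50% of each autosomal pileup was kept at random, the autosomal share came to 0.193 percentage points above that on X. The background of each peak was also cut to 50%, but to no less than the genome-wide value. The autosomal medians of 20.4 and 34.8 fragments thereby reached that value, whereas the X median in replicate 1 was 15.4, above its genome-wide 13.8. The setting thus did not reproduce X in replicate 1, and the match is no test of dose alone. By replicate the fit was looser, with 23.3% after halving against 22.2% on X in replicate 1 and 26.1% against 28.1% in replicate 2. Lower peak heights on X stay open by fold enrichment. The lower log2 difference at gene ends was -0.13 and those over all peaks -0.01 and -0.0025. However, 31.6 and 75.6% of X peaks stand at the genome-wide background, so folds on X and autosomes have unlike denominators. Median pileups were lower on X, at 41 and 58 fragments, than on the large autosomal arms, at 51.5 to 55 and 72 to 76. A halved signal would look the same from 1 DNA copy as from less acetylation per copy, and no biological explanation was tested.

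The local background under the peaks of y and its near flank was 20.3 to 25.6 fragments in replicate 1 and 33.2 to 40.6 in replicate 2, against medians of 15.4 and 27.1 elsewhere on X. Of the X peaks elsewhere, 14.0% reached the lowest of these in replicate 1 and 0.764% in replicate 2, while 36 of 1327 and 0 of 1440 reached the highest. The highest background at y was 1.66 times the X median in replicate 1 and 1.5 times in replicate 2, where that median is the genome-wide background itself and the ratio says nothing on copy number. The background was highest at the peak over the gene start. In replicate 1 it was 20.2 at 345142 to 345310 and 13.8, the genome-wide value, at 378188 to 378340. In replicate 2 it was 27.1 at 345119 to 345277. Both ranges at y include the median background of autosomal peaks, 20.4 fragments in replicate 1 and 34.8 in replicate 2. They thus stand above the X medians and not above the autosomal ones. The folds at y are taken over this background. A general level of X and any extra copies of y sequence in the transgenic line might each contribute to the excess over the X medians. They cannot be told apart here, since the replicates differ on the first and replicate 1 alone does not decide the second. Other causes were not tested.

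Wing patterning, ZP-domain and chitin, planar polarity and ecdysone response genes are long, and a longer gene is more likely to hold a peak somewhere. Against lists matched in length the adjusted p remained 0.0125, 0.0411, 0.0411 and 0.0427, so length alone does not account for the excess. At gene ends the planned test called 0 lists above by Fisher's exact test, while wing patterning passed among isolated genes (adjusted exact p = 0.00144), and planar polarity with a -log10 q of at least 5 and on autosomes alone (adjusted exact p = 0.0290 and 0.0449). Housekeeping ribosomal proteins also passed among isolated genes, and against length-matched lists at gene ends neither wing patterning nor planar polarity passed (adjusted permutation p = 0.141 and 0.0892). Peaks inside these genes may mark enhancers active in the wing, a hypothesis that was not tested and rests on a definition chosen after the data were seen.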
